A study of Mus musculus with 4 samples.

How the data were processed

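The series held 4 CUT&RUN libraries from MEL cells, each the only one of its group as the labels give it: anti-GFP in cells labelled Myb-GFP, anti-GFP in MEL, IgRab with no antibody in MEL, and anti-Myb in MEL. Peak lists of the first and the last were analysed. The other 2 libraries were not analysed here, so no background level measured in control cells can be set beside the values.

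Per the labels' protocols, cells were bound to concanavalin A beads, permeabilized with digitonin and treated with a protein A nuclease fusion activated by calcium, and libraries were made with a commercial low-input kit. The submitters' processing notes name Trim Galore 0.6.6, STAR 2.7.9a, SAMtools 1.11, Picard 2.17.11, HOMER 4.10.3, deepTools 3.4.2 and the mm9 genome build. The roles of these tools, the peak threshold, duplicate handling and the control library used in peak calling are not given in the sources used here. A control or duplicate filter chosen by the authors decides which peaks are listed, and the number of peaks would change with it. Each list belongs to 1 library, per the labels, so peaks of replicates were not pooled.

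Each file had 6 tab-separated columns without a header: chromosome, start, end, peak name, score and strand. The score deposited by the authors was 1 for every peak, so it carries no height. The start and end deposited by the authors gave every peak of a list the same width, 337 bp for anti-GFP and 313 bp for anti-Myb. The peak name was the chromosome and a running number. Sequence names such as chrUn_random and chr9_random are of the mm9 type. Coordinates are printed 1-based on mm9. No peak overlapped or touched another of its own list, and the smallest distance between centres was 637 bp in the anti-GFP list and 568 bp in the anti-Myb list. Read depth per library is unknown. Exact 95% binomial (Clopper-Pearson) intervals on shares of peaks cover the counting of peaks only.

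From these coordinates the following were computed with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1. Peaks were shared if they overlapped by at least 1 bp, and the counts were checked with bedtools 2.31.1, which gave the same 607. For a random level, the anti-Myb peaks were placed 1000 times within their chromosomes, between the outermost peaks of both lists, since no mm9 chromosome lengths were used here. A local random level moved each anti-Myb peak by 10 to 100 kb to either side. List positions of shared and unshared peaks were compared by the difference in medians with 100000 resamples, two-sided. The design fixed before the data were examined ranked peaks by score or, where scores were constant, by width. Both were constant, so the row order was used in their place. The chromosomes of the 2 lists were compared by a chi-square statistic with peaks permuted between lists 100000 times, and each of 20 chromosomes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment. The analyses of centre distances, local groups and 10 Mb windows were added after the data were seen. Correlations were tested by permutation.

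Tests were checked on simulated lists of the real sizes. With 20% of a simulated anti-Myb list of 3410 peaks planted beside anti-GFP peaks, 20.3% were found to overlap. The planted peaks lay within 50 bp of an anti-GFP centre and were bound to overlap, so this checked the counting only. Of 40 pairs of independent lists, 5% had p under 0.05. The independent lists were placed evenly at random within chromosomes, as the test assumes. The real peaks gathered locally, and the false positive rate for such lists was not checked. With chromosome 14 planted at 50% of its anti-GFP share, 84% of 100 simulated pairs passed the chromosome test, against 5.9% of 1000 unchanged pairs. Of 100 simulated sets of distances that fell steadily, 1% passed the test for a rise with distance.

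A plan fixed before the data were examined named the 10 shared peaks with the best mean rank in both lists. It also named the 5 best-ranked peaks of each list without an overlap. Its ranks were by score or width, so ranking these regions by row order was chosen after the data were seen. The same plan fixed 13 gene lists, the shares of promoter, exon, intron and intergenic peaks, 5 sequence motifs including the MYB motif, and the peaks around Myb itself. All of these need an mm9 annotation or genome. The gene table used here is of the GRCm38 assembly, and coordinates were not converted between builds, so none of these analyses was run and no gene is assigned to a peak. The alternatives tried were stricter and looser overlap, chromosomes 1 to 19 and X only, the first 50% or 25% of each list, peaks within 10 kb counted once, other windows, and leaving out 3 segments.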

Results

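Chromatin occupancy was profiled by CUT&RUN in MEL cells, a mouse erythroleukemia line blocked at an early erythroid stage. CUT&RUN releases DNA next to an antibody-bound protein with a tethered nuclease and sequences it, so that a bound site appears as a local pile of fragments. The series held 4 libraries, with 1 library per group. An anti-GFP library came from MEL cells labelled Myb-GFP, and a second anti-GFP library came from MEL cells without that label. Another library was labelled IgRab with no antibody, and the last was made with an antibody against Myb in MEL cells. MYB is a DNA-binding transcription factor of immature blood cells. Peak lists of the anti-GFP library in Myb-GFP cells and of the anti-Myb library were analysed, and the other 2 libraries, which had no peak list among the files analysed here, were not used. The anti-GFP list held 7327 peaks of 337 bp and the anti-Myb list 3410 peaks of 313 bp, a ratio of 2.15. These peaks covered 2.47 Mb and 1.07 Mb of mm9. No read depth or peak height was available, so peaks were present or absent, and the number of reads behind a peak is unknown. With 1 library per antibody there were no biological replicates. Every p-value below compares the listed regions with random or regrouped regions and says nothing about the spread between cultures.

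The first comparison asked how many regions were listed with both antibodies. The Myb-GFP label is read here as cells that carry Myb tagged with GFP, which the labels do not spell out. A peak of the other list overlapped 607 of the 3410 anti-Myb peaks, which is 17.8% (exact 95% interval 16.5% to 19.1%). The same 607 overlaps were 8.28% of the anti-GFP list (7.66% to 8.94%). When the anti-Myb peaks were placed at random within their chromosomes 1000 times, a mean of 7.13 ± 2.697 (SD) peaks overlapped, and the highest of the placements gave 16. The overlap was therefore 85.1 times the random level (one-sided permutation test, p = 0.001, the smallest that 1000 placements can give). Moving each anti-Myb peak by 10 to 100 kb within its own neighbourhood raised the random level to 21.7 ± 4.49 (SD) peaks, and the overlap was 28.0 times that level (permutation p = 0.001). Neither random level kept peaks to open or mappable sequence. The folds therefore cannot separate a shared target from open chromatin or background common to both libraries. The remaining 2803 anti-Myb peaks and 6720 anti-GFP peaks overlapped nothing in the other list. The share depended on the tolerance: 31.7% of anti-Myb peaks (30.2% to 33.3%) had an anti-GFP peak once a gap of up to 500 bp was allowed, and 6.74% (5.93% to 7.64%) when centres had to lie within 100 bp.

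Anti-Myb peaks were also concentrated near anti-GFP peaks at longer range. An anti-GFP centre lay within 10 kb of 46.7% of the anti-Myb peaks, against 5.73% of randomly placed ones, and most of this excess lay within 1 kb, where the values were 32.5% and 0.643%. The nearest anti-GFP centre was 1 to 10 kb away for 14.2% of the anti-Myb peaks, against 5.08% at random. Within 100 kb, closer peaks included, the values were 85.6% and 30.4%. These random values came from placement within whole chromosomes, and no local random level was computed for them. For overlap the local level was the higher one, at 21.7 peaks against 7.13. Centres of the 607 overlapping pairs were a median of 143 bp apart, and 118 of them (19.4%) were within 50 bp. Counting every anti-GFP and anti-Myb pair, 229 pairs had centres less than 100 bp apart and 305 were 100 to 250 bp apart. The range from 250 to 400 bp held 164 pairs, and the equally wide range from 400 to 550 bp held 273. Beyond this the number dropped to 102 pairs between 550 and 700 bp and 72 between 700 and 1000 bp.

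**Figure D1:**
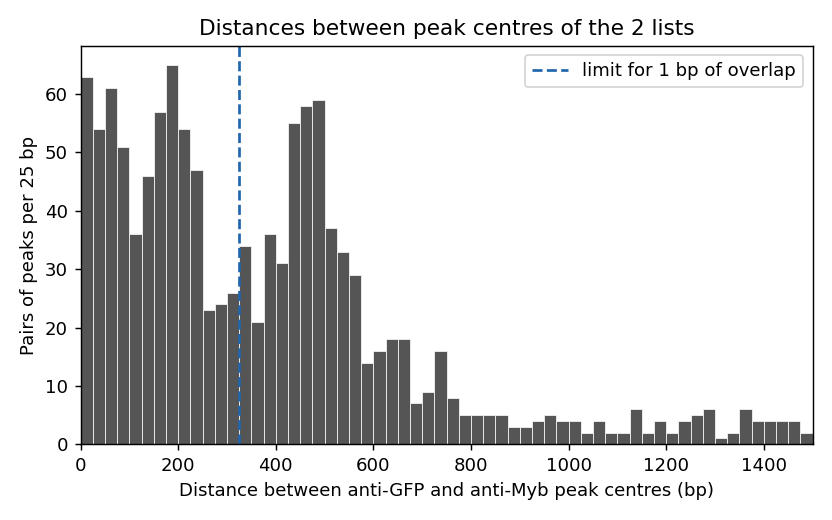
Number of anti-GFP and anti-Myb peak pairs (y axis, pairs per 25 bp) against the distance between their centres (x axis, bp), over both complete lists. The dashed line marks the largest distance at which the peaks still overlap; the 273 pairs from 400 to 550 bp lie beyond it and exceed the 164 pairs from 250 to 400 bp.

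The second comparison asked where shared regions stood within each list. Both files gave every peak a score of 1 and one width, so the ranking by score or width fixed in advance was replaced by the row order of the file. Within each assembled chromosome the row order followed the running number in the peak names, with Spearman's rho between 0.989 and 0.994 in the anti-GFP list and between 0.983 and 0.992 in the anti-Myb list. The files do not state what the rows are sorted by. Shared peaks stood earlier than unshared ones in both lists. In the anti-GFP list the median shared peak stood 31.8% of the way down and the median unshared peak 51.6%, a difference of -19.9 percentage points (two-sided permutation test, p = 1e-05, the smallest that 100000 resamples can give). In the anti-Myb list the medians were 42.5% and 51.9%, a difference of -9.47 points (permutation p = 3e-05). The first 10% of the anti-Myb list had 103 shared peaks of 341 (30.2%, 25.4% to 35.4%), and the last 10% had 37 of 341 (10.9%, 7.76% to 14.6%). The first 10% of the anti-GFP list had 148 shared peaks of 733 (20.2%, 17.3% to 23.3%), and the last 10% had 25 of 732 (3.42%, 2.22% to 5.00%). Across the 607 pairs the positions in the 2 lists were weakly related (Pearson's r = 0.23, Spearman's rho = 0.24, permutation p = 1e-05 for each). This correlation is across peaks, which are not independent replicates.

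**Figure D2:**
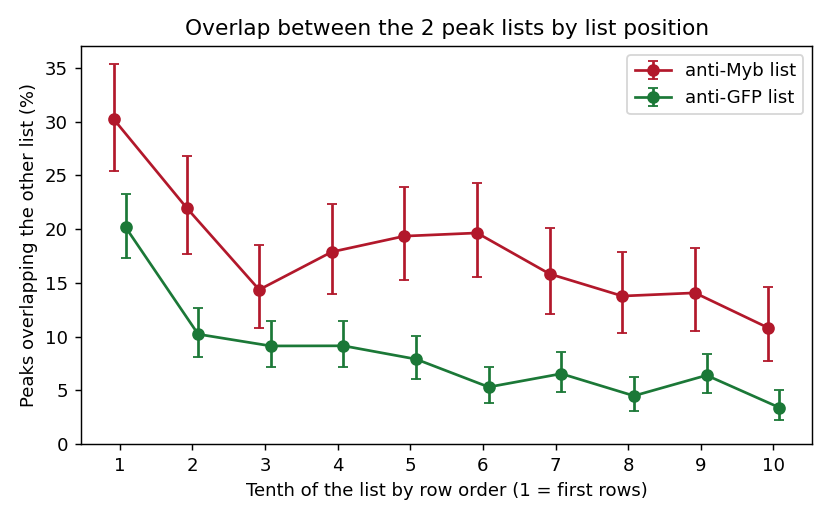
Share of peaks that overlap the other list (y axis, percent, with exact 95% binomial intervals) in 10 equal parts of the anti-Myb and anti-GFP lists by row order (x axis). The share falls from 30.2% to 10.9% in the anti-Myb list and from 20.2% to 3.42% in the anti-GFP list.

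Of the shared regions, the pair with the earliest mean position over both lists lay on chromosome X, at 166436069 to 166436405 in the anti-GFP list and 166436091 to 166436403 in the anti-Myb list. It was row 14 of the anti-GFP list and row 1 of the anti-Myb list, with centres 10 bp apart. The next pair lay less than 10 kb away on the same chromosome, at 166429277 to 166429613 (row 11) and 166429044 to 166429356 (row 4). The third was on chromosome 8, where the anti-GFP peak spanned 125224293 to 125224629 (row 50) and the anti-Myb peak 125224543 to 125224855 (row 14). On chromosome 17 the anti-GFP peak at 31208190 to 31208526 (row 13) overlapped the anti-Myb peak at 31208357 to 31208669 (row 32). A region of chromosome 3 near 100242767 stood at rows 39 and 21, and a region of chromosome 9 near 22018676 at rows 3 and 58. The other 4 of the 10 shared regions with the earliest mean positions began at 27801735 on chromosome 15, 44271821 on chromosome 19, 94920385 on chromosome 16 and 147515570 on chromosome 5, by the anti-GFP coordinates. The chromosome 16 region was row 340 of the anti-GFP list and row 3 of the anti-Myb list.

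Several of the earliest rows of each list had no overlapping partner. The first 2 rows of the anti-GFP list, on chromosome 19 at 29722380 to 29722716 and 29429748 to 29430084, were 235 kb and 57.3 kb from the nearest anti-Myb centre. The next unshared anti-GFP peaks were at 22193924 to 22194260 on chromosome 9, and at 96205548 to 96205884 and 95761583 to 95761919 on chromosome 3, at 64.0 kb, 68.8 kb and 75.2 kb from an anti-Myb centre. In the anti-Myb list, row 2 was a peak on chromosome 1 at 36977097 to 36977409, 14.3 kb from the nearest anti-GFP centre. Row 6, on chromosome 7 at 87353725 to 87354037, missed an anti-GFP peak narrowly, with centres 0.542 kb apart. The peaks on chromosome 2 at 152615107 to 152615419 and 31983800 to 31984112 were 41.5 kb and 109 kb away. The peak on chromosome 9 at 21117954 to 21118266 was 7.15 kb away.

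The third comparison set the chromosomes of the 2 lists side by side. Chromosome 11, known as a gene-rich mouse chromosome, held the most peaks in both lists, with 647 anti-GFP peaks (8.84%) and 301 anti-Myb peaks (8.84%). Per 10 Mb of the span between the outermost peaks, it held 54.7 anti-GFP and 25.5 anti-Myb peaks. Chromosome 19 followed with 47.4 and 24.9, and chromosome 17 with 43.8 and 23.1. Chromosome X was the sparsest, with 11.2 and 4.26. The distributions over the 20 chromosomes were not shown to differ (chi-square 25.4, permutation p = 0.15). Chromosome 14 held 228 anti-GFP and 75 anti-Myb peaks, an odds ratio of 0.70 (95% interval 0.53 to 0.92). Chromosome 3 held 290 and 169, an odds ratio of 1.27 (1.04 to 1.54). Fisher's exact test, two-sided, gave unadjusted p = 0.0084 and 0.018 for these, the only 2 of 20 chromosomes under 0.05. After Benjamini-Hochberg adjustment none passed, with 0.17 for chromosome 14 and 0.18 for chromosome 3. The share of anti-Myb peaks that overlapped the anti-GFP list lay between 13.3% on chromosome 14 and 23.5% on chromosome X. Sequences outside chromosomes 1 to 19 and X held 8 anti-GFP and 6 anti-Myb peaks, and 2 of these anti-Myb peaks were shared.

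**Figure D3:**
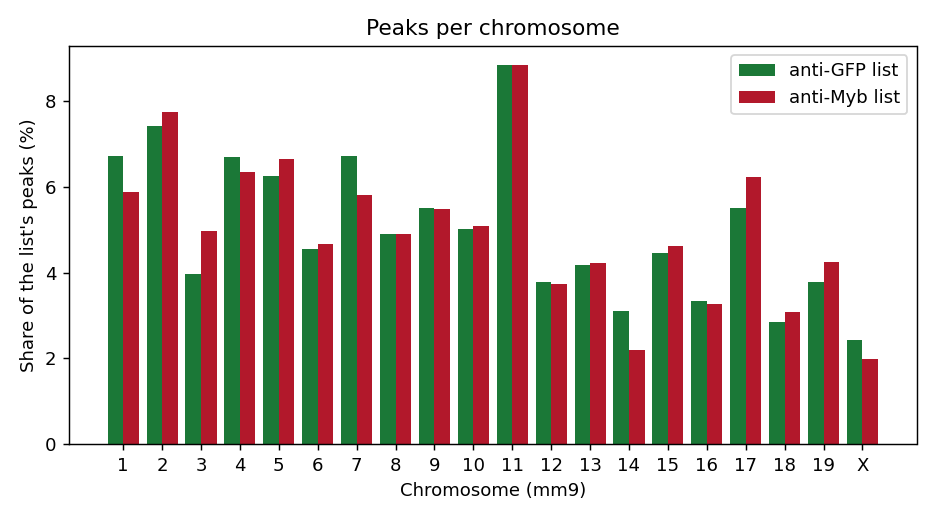
Share of each list's peaks (y axis, percent of the peaks on chromosomes 1 to 19 and X) on each mm9 chromosome (x axis), 1 library per list. Chromosome 11 holds 8.84% in both lists, and chromosome 14 holds 3.12% of anti-GFP and 2.20% of anti-Myb peaks.

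Peaks also gathered locally. In the anti-Myb list 380 pairs of adjacent peaks had centres within 10 kb, which involved 728 peaks. This was 7.40 times the mean of 51.4 pairs in 200 random placements (permutation p = 0.005, the smallest they can give). In the anti-GFP list there were 718 such pairs, involving 1365 peaks, 3.15 times the random mean of 228 pairs (permutation p = 0.005). The groups with the most peaks are named after their values were seen. A 36.4 kb stretch of chromosome 17, from 15097158 to 15133586, held 9 anti-GFP peaks and no anti-Myb peak. A second stretch of chromosome 17, from 34324691 to 34361601, held 6 anti-GFP peaks, of which 2 were shared. A 19.97 kb stretch of chromosome 6, from 70742485 to 70762457, held 5 anti-GFP peaks and no anti-Myb peak. The anti-Myb group with the most peaks held 5 on chromosome 13, from 64533803 to 64551467, with no anti-GFP peak.

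The early rows of both lists came from some of the same segments. In the 136 windows of 10 Mb with at least 10 peaks of each list, the median position in the anti-GFP list and that in the anti-Myb list were related across windows (Pearson's r = 0.55, Spearman's rho = 0.45, permutation p = 1e-05 for each). Without the 2 windows farthest from the anti-GFP median r was 0.52. On chromosome 9 from 20 to 30 Mb the median anti-GFP peak stood 8.005% and the median anti-Myb peak 7.60% of the way down, over 34 and 19 peaks. On chromosome 3 from 90 to 100 Mb the medians were 16.3% and 15.3%, over 54 and 29 peaks. On chromosome 19 from 40 to 50 Mb they were 14.6% and 23.3%, over 62 and 58 peaks. Within the chromosome 9 window, the peaks in the first 10% of the anti-GFP list lay between 20449382 and 22280686, a run of 1.83 Mb, and those of the anti-Myb list between 20833851 and 22018878. The anti-GFP and anti-Myb runs were longer in the chromosome 3 window, at 3.06 Mb and 1.58 Mb. In the chromosome 19 window they were 5.71 Mb and 5.83 Mb. These 3 windows, picked after the data were seen, held 2.05% of the anti-GFP list and 8.06% of its first 10%. Of the anti-Myb list they held 3.11%, and 11.7% of its first 10%. Some windows stood early in the anti-GFP list alone. On chromosome 1 from 90 to 100 Mb the anti-GFP and anti-Myb medians were 10.3% and 46.1%, over 18 and 11 peaks. On chromosome 3 from 80 to 90 Mb they were 20.5% and 51.6%, over 49 and 21 peaks. Others stood earlier in the anti-Myb list. On chromosome 17 from 10 to 20 Mb the anti-GFP and anti-Myb medians were 56.2% and 27.7%, over 33 and 13 peaks. On chromosome 8 from 80 to 90 Mb they were 52.6% and 28.1%, over 53 and 23 peaks. Windows and peaks are not independent replicates.

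**Figure D4:**
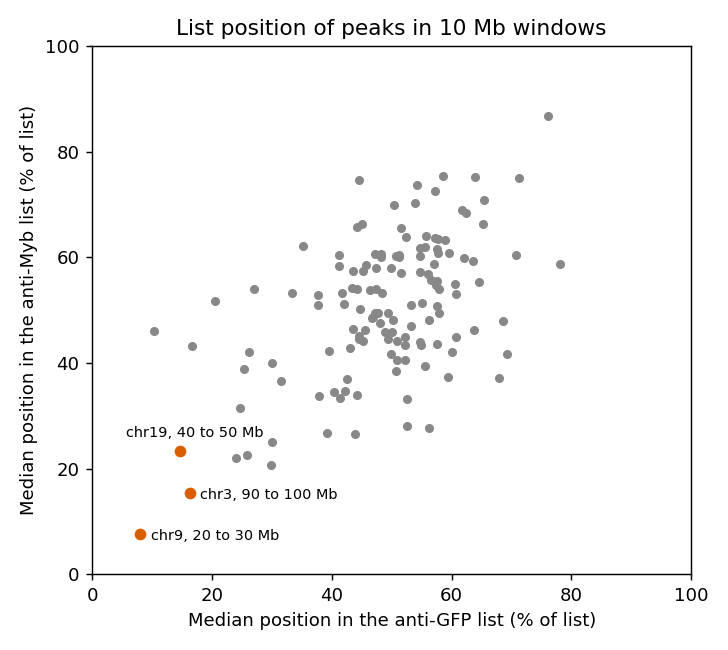
Median list position of the anti-GFP peaks (x axis, percent of the list from its first row) and of the anti-Myb peaks (y axis, same unit) in 136 windows of 10 Mb, each point 1 window. The 3 windows marked in orange, on chromosomes 9, 3 and 19, stand early in both lists.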

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

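The alternatives that use row order, a centre distance of 1 kb, the 3 segments, other windows, the removal of chromosome 14, or the gap and the local background together were chosen after seeing the data. The overlap stayed above the random level in both lists under all 11 alternatives, from 19.8 times, with a gap of up to 500 bp against the local background, to 102 times (permutation p = 0.001 in each). The share itself followed the definition of overlap. Of anti-Myb and anti-GFP peaks, respectively, 10.4% and 4.82% were shared when 50% of the shorter peak had to be covered, 9.47% and 4.41% when 50% of each peak had to be, and 6.74% and 3.14% with centres within 100 bp. The shares were 31.7% and 14.97% with a gap of up to 500 bp and 32.5% and 15.3% with centres within 1 kb. Taking the first 50% of each list by row order gave 15.4% and 7.15%, and the first 25% 13.3% and 6.17%; these settings remove possible partners as well as peaks. Chromosomes 1 to 19 and X only, and leaving out the 3 segments, left both shares within their intervals. Shared peaks stood earlier in both lists under all 5 alternatives, and the highest permutation p was 0.00031. The chromosome comparison stayed above 0.05 under all 4 alternatives, with p up to 0.49. The odds ratio of chromosome 14 ranged from 0.64 to 0.72 with unadjusted p up to 0.033 under 3 alternatives. The correlation of list positions across windows ranged from 0.37 to 0.47 over 6 alternatives. Merging touching peaks had nothing to merge. Splits by score or width, promoter-preserving placement, and all alternatives for gene positions, gene lists and motifs were not run, for want of peak heights and of an mm9 annotation. Depth limits what an absent peak shows: without read counts, a region missing from a list was not detected under the authors' threshold and is not shown to be unbound.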

Other observations

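All tests in this part were chosen after the main results were seen; the values behind 2 of them, on second peaks beside an overlapping pair and on dense clusters, had not been seen when the tests were chosen.

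The running numbers in the peak names left gaps in both lists. The highest numbers, summed over sequences, came to 40213 for anti-GFP and 11005 for anti-Myb, of which the listed peaks were 18.2% and 30.99%. Chromosome 19 had the highest number per listed peak in both lists: its numbers reached 3737 for 276 anti-GFP peaks and 1492 for 145 anti-Myb peaks. Chromosome 3 reached 3609 for 290 and 994 for 169 peaks, and chromosome 9 reached 3054 for 403 and 1250 for 187. On chromosomes 14 and 12 alone the number per listed peak was higher in the anti-Myb than in the anti-GFP list, at 6.24 against 4.04 and 5.25 against 4.89. On chromosome 2 the numbers reached only 1938 for 543 and 470 for 264 peaks. Across the 20 chromosomes the highest number per listed peak was related between lists (Pearson's r = 0.77, permutation p = 0.00091; Spearman's rho = 0.67, p = 0.0018). Without chromosomes 19 and 3, the 2 farthest from the median of the anti-GFP values, r was 0.45 (p = 0.051) and rho 0.57 (p = 0.014). The files do not say what the missing numbers were. Of 269 windows of 10 Mb, 1 differed in its number of peaks between lists after Benjamini-Hochberg adjustment: chromosome 19 from 40 to 50 Mb, with 62 anti-GFP and 58 anti-Myb peaks (odds ratio 2.03, Fisher's exact test, adjusted p = 0.042). This test takes peaks as independent, although peaks gathered locally, and its adjusted p lies close to 0.05.

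Most peaks of each list overlapped no peak of the other. A list threshold that leaves out weak peaks would, as the whole cause, leave nearly all of the earliest anti-Myb peaks with an anti-GFP partner. In the first 10% of the anti-Myb list only 45.7% of peaks (40.4% to 51.2%) had an anti-GFP centre within 1 kb. The line for nearly all was 90%, set after the values were seen. This argues against the explanation only if row order follows strength and sites strong in the anti-Myb library are also strong in the anti-GFP library. The second condition is doubtful, because positions of the 607 overlapping pairs were weakly related (Spearman's rho = 0.24). Centres placed apart within the same element are argued against as the whole cause. A gap of up to 500 bp raised the share of anti-Myb peaks with a partner to 31.7%, and no further than 33.3% by its interval. Such centres may account for part of the pattern, because that share was 17.8% without the gap. Different antibodies, a different cell line and a difference in depth between the libraries remain open, because antibody and line changed together and each had 1 library. The list threshold stays open too, and so does the authors' control or duplicate filter, which is not known. The anti-GFP library of cells without the Myb-GFP label would bear on peaks that do not depend on Myb-GFP, and was not analysed here.

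Centres of neighbouring anti-GFP and anti-Myb peaks lay apart at preferred distances. Random placement error around one site would make pairs steadily rarer with distance. The largest rise between adjacent ranges of equal width, searched over all positions up to 1000 bp and widths from 50 to 200 bp, was 5.79 (difference in pairs over the square root of their sum). None of 1000 sets simulated from the best steadily falling fit reached this, and their highest was 4.15. This argues against placement error as the whole pattern, and it does not rest on ranges picked from the plot. A second peak beside a pair that already overlaps was found in only 1.47% of the pairs 400 to 550 bp apart (4 of 273; 0.401% to 3.71%). This counts those pairs directly, so it argues against such peaks as their source, whatever role the spacing of peaks within a list had in keeping them few. A candidate explanation that stays open is that both libraries mark the same elements of about 1 kb and the caller keeps a different summit in each; no signal track was used to test it, and no biological explanation was tested.

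Peaks of the same 10 Mb windows stood early in both lists. The same sites being present in both lists is not the whole cause: with all peaks within 1 kb of the other list left out, Spearman's rho across 101 windows was 0.46 (one-sided permutation p = 2e-05). A few dense clusters are not the whole cause either, since rho was 0.42 over 129 windows when peaks within 10 kb counted once (p = 1e-05). A higher number of DNA copies of these segments in this cell line is a hypothesis that remains possible. In the 10 windows with the earliest anti-GFP medians, the 163 anti-Myb peaks that lay over 1 kb from any anti-GFP peak stood at a median of 30.3% of the list (bootstrap 95% interval 23.4% to 37.4%). By window this median ran from 9.11% on chromosome 9 (20 to 30 Mb) to 61.9% on chromosome 3 (80 to 90 Mb). The interval counts peaks, not windows. Because the windows were picked by their anti-GFP medians, the pooled value repeats in part the correlation above. Regulatory regions with higher occupancy would give the same value, so the 2 cannot be told apart without a measure of DNA copy number. A karyotype or input library is what a follow-up on copy number would need. Background signal common to both libraries was not tested either. The IgRab library and the anti-GFP library of cells without the Myb-GFP label would bear on that background, and were not analysed here.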
